A study of Mus musculus with 9 samples.

How the data were processed

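Polyadenylated RNA from whole livers of male C57BL/6J mice was sequenced, 3 samples in each of 3 groups. Mice of the GF group stayed germ-free. Mice of the GF+SCFA group stayed germ-free and drank water with 67.5 mM acetate, 25.9 mM propionate and 40 mM butyrate, the main short-chain fatty acids of gut fermentation. ConvD mice were germ-free mice given cecal contents of conventionally raised donors by gavage. All 9 mice ate chow. The labels disagree on age: the design text gives 14 weeks, and the growth protocol gives gavage at 15 weeks, 4 weeks of colonisation and dissection at 19 weeks. Per the labels' protocols, mice were housed in groups by colonisation status, so cage and group are not separable here, and no time of day of dissection is given. The design text calls the 3 samples of a group biological replicates, and the labels do not name the animal of each, so the p-values measure the spread between these samples.

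Per the labels' protocols, RNA was extracted with Qiagen columns and libraries were made with the Illumina TruSeq Stranded mRNA kit. Per the submitters' processing notes, the authors used Bowtie2 and RSEM 1.2.23 with the mouse build mm9. The version of Bowtie2 and the strand setting of RSEM are not given in the sources used here, so reads of overlapping antisense genes may be shared. The deposited tables hold 1 row per gene symbol, 20325 in all and the same in each sample, with estimated counts (RSEM expected counts), TPM and lengths. The expected counts deposited by the authors are not normalised, and 32.8% of those above 0 are not whole numbers, because RSEM divides reads that match several genes. The deposited TPM values, per the file headers, are normalised by the authors for gene length and depth. In members of near-identical families (the Mup, Cyp2c, Cyp3a, Gsta, Gstm and Acot families, hemoglobins and histocompatibility genes) this division makes the value of a single gene uncertain. FPKM values were not used here. Symbols are those of the files. The 1162 entries of the gene lists were matched by symbol, older symbol or RefSeq accession through a table of the assembly GRCm38.p6, and 1151 were found. No coordinates are given, because the files carry none and the build differs from that of the reference.

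Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 12037 genes. Library sizes were scaled by trimmed mean of M values (TMM). A no-intercept model with the 3 groups and all 9 samples was fitted with robust quasi-likelihood dispersions (6 residual degrees of freedom), and each pair of groups was compared with the quasi-likelihood F test. The p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Printed expression values are CPM, counts scaled to the TMM-normalised library total, given as mean ± SD over 3 samples. A standard error (SE) of a log2 fold change is the fold change divided by the square root of its F statistic.

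Lists of genes for 35 processes and 15 cell types were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where a choice is said to be later. Lists with at least 3 tested members, 47 of 50, were tested with camera (limma 3.58.1) with a preset correlation of 0.01. The same test with an estimated correlation and the rotation test fry were run beside it. The count of changed members is given over all genes tested and adjusted over the list alone. Some genes belong to several lists, among them Pck1, Tat, Gsta1, Slc40a1, Psmb8, Psmb9 and Tap1. They are counted in each, so the lists are not independent. With the estimated correlation, 0 lists passed in any comparison, and its adjusted p is printed beside each list whose count is given.

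Genes are named by rule. In each comparison these are the 10 largest changes in each direction among called genes with a mean expected count of at least 50 and no overlap between the groups, and up to 4 members of each list with the smallest adjusted p. Genes named outside this rule are other members of the fixed lists, or genes said to be chosen after their values were seen. For a gene without a count in a group, a bound was computed against a floor of 3 counts per library. Some genes that meet the rule are not reported here. Floors and bounds cover counting error only.

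Depth was 18193071 to 21627696 expected counts per sample, and the 10 largest genes held 20.9% to 23.3% of them. TMM factors ranged from 0.935 to 1.06. The chi-square per degree of freedom between samples of a group was 11.4 to 54.5, so no 2 libraries of a group were copies. The biological coefficient of variation was 10.6%. Counts were simulated with these means, depths and spreads, and with 49 or 50 tested genes changed at each fold in each treatment. The ConvD against GF test over 11962 genes recovered 12.2% of genes changed 1.25-fold, 71.4% at 1.5-fold, 83.7% at 2-fold and 96% at 4-fold. For GF+SCFA against GF the shares over 11962 genes were 6%, 52%, 89.8% and 98% at the same folds. For ConvD against GF+SCFA they were 16.2%, 67.7%, 90.8% and 98%. Of the calls in these simulations, 5.8%, 5.4% and 8.8% were unchanged genes. The shares recovered depend on how many genes change, which in the real comparisons is not known. Where fewer genes change the adjusted threshold is stricter, so the shares may be too high for GF+SCFA against GF.

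Alternatives were other scalings (median-ratio size factors, upper quartile, library totals), no filter, a mean count of at least 50, DESeq2 1.42.0, limma voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and an offset for effective length. Others were non-robust spreads, a test against a fold change of 1.2, the 6 samples compared alone, the replicate number as a block, and each sample left out. Fold changes on the log2(TPM + pseudocount) scale understate changes of low genes. For the relation of the ConvD and GF+SCFA responses, 100 data sets without group effects were simulated for the same 3 GF controls, and 100 more for each fit without 1 GF sample, added after seeing the data. A further estimate, on differences of mean log2 CPM, split the 3 GF samples so that no control was shared (6 splits, chosen after seeing the data). Figures were drawn with matplotlib 3.10.9.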

Results

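The series measured liver messenger RNA of germ-free mice (GF), germ-free mice supplied with short-chain fatty acids in the drinking water (GF+SCFA) and germ-free mice colonised with a donor microbiota (ConvD), with 3 livers per group, all on chow. Totals of expected counts were 18704946, 21627696 and 20814962 in the GF libraries, 18193071, 20080417 and 18666245 in the GF+SCFA libraries and 19452484, 19956632 and 18448840 in the ConvD libraries. In a principal component analysis of the 500 most variable genes, the first component held 42.1% of the variance. The ConvD livers scored 12.8 to 18.7 on it, the GF livers -6.29 to -4.44 and the GF+SCFA livers -13.1 to -8.38. On the second component (14.6%), GF replicate 3 scored 1.2, between the other GF livers at 9.25 and 12.6 and the GF+SCFA livers at -7.48 to -1.82.

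**Figure D1:**
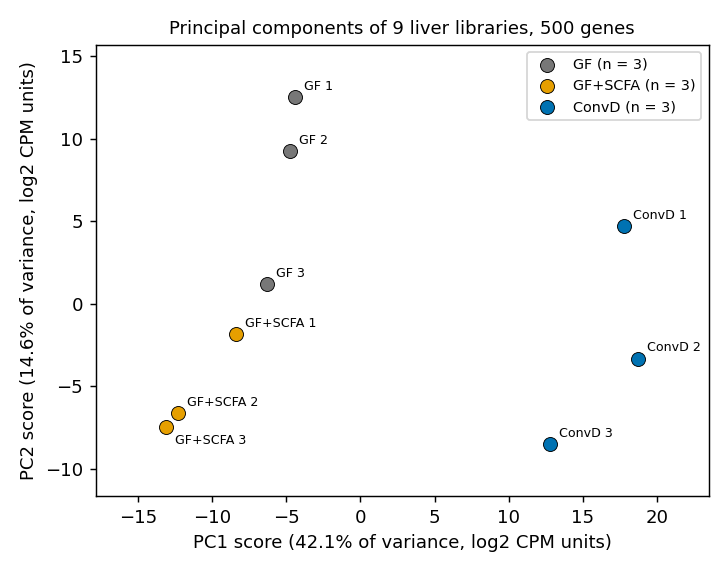
Scores of the 9 liver libraries on the first and second principal components (42.1% and 14.6% of the variance) of log2 CPM over the 500 most variable genes, with 1 point per library, coloured by group. The 3 ConvD livers lie above 12 on the first component and all GF and GF+SCFA livers below 0.

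The comparison of ConvD with GF livers addresses which liver transcripts differ once germ-free mice carry a microbiota. Colonised livers had more transcripts of Cyp3a11, of 20 of 37 interferon-stimulated genes and of 10 of 16 Kupffer cell and macrophage markers. They also had more transcripts of 7 of 20 NRF2 and glutathione genes and of 5 of 11 monocyte and neutrophil markers. They had fewer transcripts of Cyp7a1, of 8 of 21 clock genes, of 6 of 20 glucocorticoid and fasting genes, of 5 of 18 gluconeogenic genes and of 10 of 21 endoplasmic reticulum chaperone genes. None of these lists passed as a whole with an estimated correlation (adjusted p = 0.106 to 0.387). Each passed with fry, which does not set the members against other genes (fry adjusted p = 0.00148 to 0.0479). In total 1544 of 12037 genes changed, 714 higher and 830 lower in ConvD, and 160 of these changed at least 2-fold (117 higher, 43 lower). At an unadjusted p under 0.05 there were 3437 genes. The groups did not overlap in 31.6% of genes, where chance gives 10% on average. Genes are not independent, so a single split can lie far from this average, and the share was not computed for other splits. Small changes depended on the scaling: 46.2% of calls were higher with TMM, 66.1% of 1601 calls with upper-quartile factors and 73.1% of 1452 calls with library totals, which moved the median gene by 0.06 and 0.08 on the log2 scale. Without ConvD replicate 2 the count was 849, without GF replicate 1 it was 918 and without ConvD replicate 1 it was 936.

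Cyp3a11, the main mouse cytochrome P450 induced through the pregnane X receptor, rose from 546 ± 195 CPM in GF to 2146 ± 66.9 CPM in ConvD livers (SD, n = 3 each; log2 fold change 1.97, SE 0.24, adjusted p = 0.00241). Gsta1, a glutathione S-transferase, rose 5.80-fold from 1.51 ± 0.122 to 8.75 ± 1.39 CPM (adjusted p = 0.00194). Aqp8, a water channel of the hepatocyte, rose 5.49-fold from 25.3 ± 5.49 to 139 ± 52.3 CPM (adjusted p = 0.00711). Further large increases were those of the uncharacterised transcripts 3010026O09Rik (3.33-fold) and 9130409I23Rik (3.32-fold), of Lcn2, a siderophore-binding protein (3.27-fold), of Spon2 (3.22-fold) and of Cyp2c55 (3.05-fold). Chrna4, a nicotinic receptor subunit, was 6.65-fold higher (adjusted p = 0.0343), and Tubb2a 3.17-fold higher (adjusted p = 0.0464).

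Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 350 ± 79.1 CPM in GF to 124 ± 28.4 CPM in ConvD livers (log2 fold change -1.49, SE 0.22, n = 3 each, adjusted p = 0.00675). Eif4ebp3, a repressor of translation, fell from 91.7 ± 13.7 to 29.4 ± 4.08 CPM (adjusted p = 0.0018). The log2 fold change was -2.32 for Cyp2c69 and -2.29 for Cyp2c40, members of a near-identical family. It was -2.11 for Zbtb16, a transcription factor induced by glucocorticoids, -1.90 for the chaperone Hsph1 and -1.82 for Ddit4, an inhibitor of mTORC1. Pcp4l1 (-1.62), Arl4d (-1.51) and Hspa2 (-1.48) completed the 10 largest decreases. Of the 20 genes with the largest changes, 12 kept an adjusted p under 0.05 whichever liver was left out. Of the 9 such fits, the call was lost in 7 for Tubb2a, Cyp2c69 and Zbtb16 and in 6 for Chrna4. It was lost in 5 for Ddit4 and Arl4d, in 4 for Hsph1 and in 2 for Cyp2c40. The adjusted p reached 0.131 (Tubb2a without GF replicate 2).

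**Figure D2:**
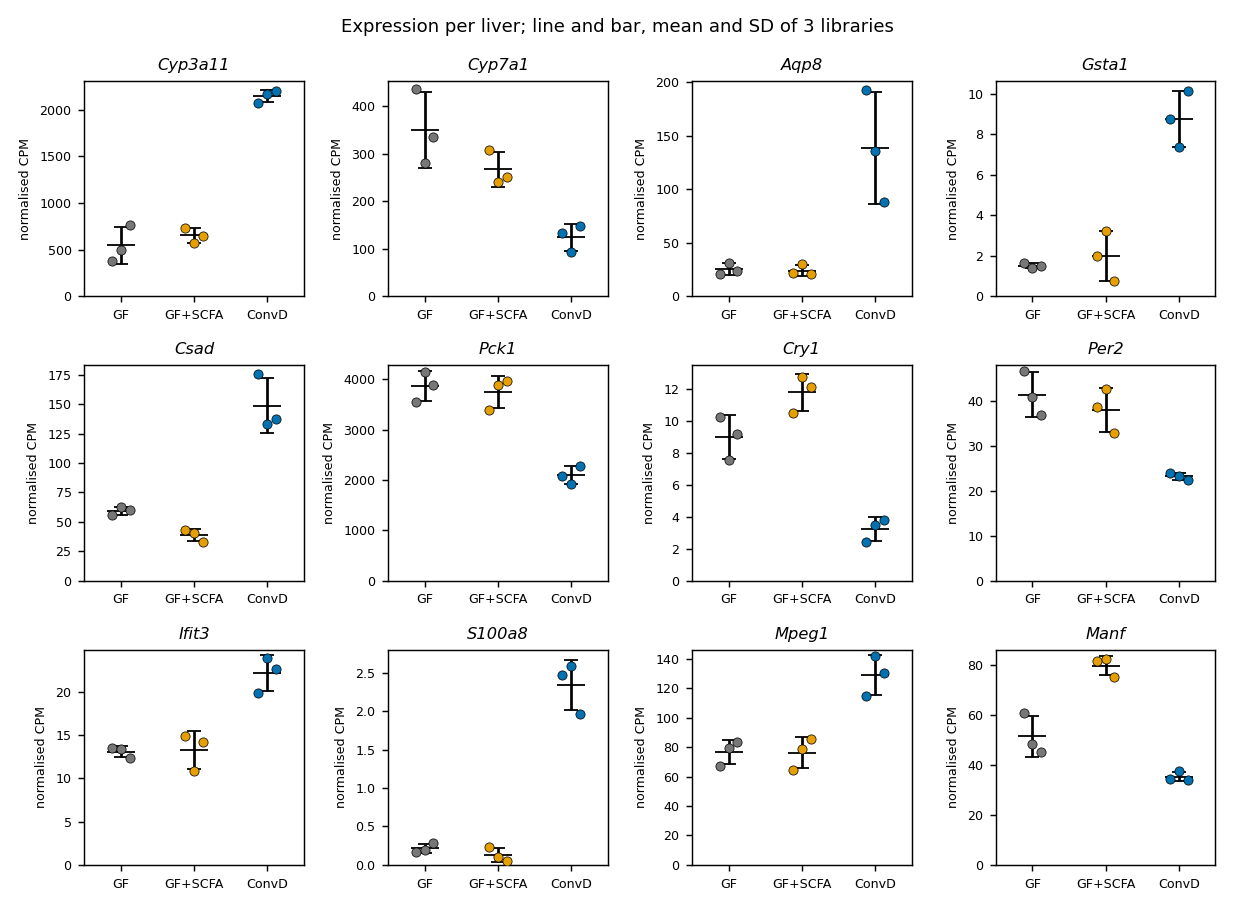
Normalised CPM (linear axes from 0) of 12 genes in each liver of the GF, GF+SCFA and ConvD groups, where points are libraries and the line and bar give the mean and SD of 3. Cyp3a11 averaged 546, 654 and 2146 CPM in the 3 groups, and Cyp7a1 averaged 350, 267 and 124 CPM.

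Among targets of the xenobiotic receptors CAR and PXR, 11 of 34 tested genes rose and 5 fell (12 and 8 adjusted over the list alone). The list as a whole did not shift (camera adjusted p = 0.0638, and adjusted p = 0.714 with an estimated correlation). Besides Cyp3a11, Cyp2c55 and Gsta1, the risers included Cyp3a59 (1.94-fold, adjusted p = 0.0004), Gstm3 (log2 fold change 1.12) and Ces2a (0.40). Por, the reductase that supplies electrons to all microsomal P450 enzymes, fell from 646 ± 70.1 to 329 ± 22 CPM (log2 fold change -0.97, SE 0.09, adjusted p = 5.05e-05). The genes of the receptors themselves, Nr1i3 (CAR, -0.60) and Nr1i2 (PXR, -0.35), also fell. Of 20 tested genes of NRF2 response and glutathione metabolism, 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.55e-08; adjusted p = 0.106 with an estimated correlation). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose 1.61-fold (adjusted p = 0.000749), Srxn1 1.56-fold (adjusted p = 0.000291) and Ephx1, microsomal epoxide hydrolase, 1.69-fold (adjusted p = 0.000911). Gstm4 was 2.26-fold higher (adjusted p = 0.00037).

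Of 15 tested genes of bile acid synthesis, 4 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.0358; adjusted p = 0.507 with an estimated correlation). Cyp2c70, which makes the muricholic acids of mice, fell from 751 ± 29.7 to 401 ± 36.3 CPM (adjusted p = 0.00194). Cyp7b1 of the alternative pathway fell as well (log2 fold change -1.07, adjusted p = 0.0325, up to 0.112 without ConvD replicate 2), a call lost in 7 of 9 fits without 1 liver. Hsd3b7 rose 1.40-fold (adjusted p = 0.00692), and Acox2 rose (log2 fold change 0.32, adjusted p = 0.00988). Of 16 tested transport genes 1 rose and 1 fell, as many adjusted over the list alone (camera adjusted p = 0.854, and adjusted p = 0.967 with an estimated correlation). Abcb11, the bile salt export pump, rose 1.40-fold (adjusted p = 0.014, 0.0546 without ConvD replicate 1). The organic anion transporter Slco1a1 fell (log2 fold change -0.33, adjusted p = 0.0106).

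Gluconeogenic genes fell in 5 and rose in 1 of 18 cases (7 and 1 adjusted over the list alone; camera adjusted p = 6.82e-05; adjusted p = 0.346 with an estimated correlation). Pck1, encoding cytosolic phosphoenolpyruvate carboxykinase, fell from 3865 ± 300 to 2095 ± 181 CPM (log2 fold change -0.88, SE 0.10, adjusted p = 0.00018). Tat, tyrosine aminotransferase, fell from 3232 ± 613 to 1464 ± 142 CPM (adjusted p = 0.00153), and the transcription factor Foxo1 fell (log2 fold change -0.74, adjusted p = 0.00018). The mitochondrial isoform Pck2 rose (log2 fold change 0.69). Of 20 genes responsive to glucocorticoids or fasting, 6 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 2.65e-07; adjusted p = 0.387 with an estimated correlation). Pck1 and Tat, counted above among the gluconeogenic genes, are among these 6 too. Tsc22d3, encoding GILZ, fell from 177 ± 22.2 CPM in GF to 111 ± 21.6 CPM in ConvD livers (adjusted p = 0.00724). The glucocorticoid receptor co-chaperone gene Fkbp5 gave a log2 fold change of -1.08 (adjusted p = 0.0372, up to 0.102 without ConvD replicate 1), a call lost in 7 of 9 fits without 1 liver. GF replicate 3 had the highest Fkbp5 of the GF livers, 82.4 CPM against 45.3 and 52.8 CPM.

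Of 25 tested genes of fatty acid synthesis, 4 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00645; adjusted p = 0.735 with an estimated correlation). Pnpla3, a lipid droplet protein induced by SREBP1c, was low in all livers but rose from 0.230 ± 0.0873 to 2.28 ± 1.33 CPM (adjusted p = 0.0039). Khk, ketohexokinase of fructose metabolism, rose 1.38-fold (adjusted p = 0.00659), and Dgat2 fell (log2 fold change -0.50, adjusted p = 0.000854). Acly, ATP citrate lyase, was 1.61-fold higher (adjusted p = 0.0347, up to 0.105 without GF replicate 3), a call lost in 7 of 9 fits without 1 liver. Of 41 genes of fatty acid oxidation and PPAR-alpha response, 2 rose and 4 fell (3 and 5 adjusted over the list alone), and the list did not shift (camera adjusted p = 0.475, and adjusted p = 0.923 with an estimated correlation). Plin2, which coats lipid droplets, rose 1.64-fold (adjusted p = 0.000726), and Cpt1a, which brings long-chain fatty acids into mitochondria, fell (log2 fold change -0.50, adjusted p = 0.00916).

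Of 37 tested interferon-stimulated genes 20 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.63. Camera gave an adjusted p = 3.58e-17, and an adjusted p = 0.179 with an estimated correlation. Ifit3, an interferon-induced RNA-binding protein, rose 1.69-fold (adjusted p = 0.00134), and Isg15, a ubiquitin-like modifier, 1.69-fold (adjusted p = 0.00152). The immunoproteasome gene Psmb9 rose 1.68-fold (adjusted p = 0.00109). Psmb9, Psmb8 and Tap1 belong to this list and to that of antigen presentation, and are counted among the risers of both. Of 23 antigen presentation genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.000104; adjusted p = 0.446 with an estimated correlation), among them the peptide transporter Tap1 (1.62-fold, adjusted p = 0.00366). Tlr5, the receptor of bacterial flagellin, rose 1.57-fold (adjusted p = 0.00289), while the sensing genes as a list did not shift (camera adjusted p = 0.0689; adjusted p = 0.644 with an estimated correlation; 2 of 24 rose and 1 fell, and as many adjusted over the list alone).

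Markers of macrophages, including Kupffer cells, the resident macrophages of the liver, rose in 10 of 16 cases and fell in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 6.54e-10, and adjusted p = 0.297 with an estimated correlation). The list mixes the 2 kinds of marker, so its count does not tell resident from other macrophages. Mpeg1 rose 1.68-fold (adjusted p = 0.00178), Cd68 1.60-fold (adjusted p = 0.00481), C1qc 1.59-fold (adjusted p = 0.00875) and the iron exporter Slc40a1 1.55-fold (adjusted p = 0.000238). Of 11 monocyte and neutrophil markers, 5 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 1.58e-09; adjusted p = 0.114 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils, rose from 0.214 ± 0.061 to 2.34 ± 0.331 CPM (adjusted p = 7.28e-05), and S100a9 rose too (log2 fold change 3.25, SE 0.38, adjusted p = 0.000257). Ltf, a neutrophil granule protein, had no count in any GF library and 1.01 ± 0.42 CPM in ConvD, at least 6.69-fold higher than 3 counts per GF library. The hemoglobin gene Hba-a1 was 146, 717 and 363 CPM in the ConvD livers and 124 to 186 CPM in the GF livers, and did not pass (log2 fold change 1.48, adjusted p = 0.157). The immunoglobulin joining chain Igj rose 3.73-fold (adjusted p = 0.00182), with 1 of 6 B and plasma cell markers passing (2 adjusted over the list alone; camera adjusted p = 0.00369; adjusted p = 0.227 with an estimated correlation).

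Clock genes fell in 8 of 21 cases and rose in 1 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00022; adjusted p = 0.106 with an estimated correlation). Cry1, a repressor of the clock, fell from 9.01 ± 1.36 to 3.24 ± 0.727 CPM (log2 fold change -1.48, SE 0.17, adjusted p = 0.00018). Per2 fell from 41.5 ± 5.01 to 23.2 ± 0.788 CPM (adjusted p = 0.000353), and the deadenylase gene Ccrn4l fell (log2 fold change -1.27, adjusted p = 0.00114). The member that rose was the repressor Bhlhe41 (log2 fold change 1.48). Of 21 endoplasmic reticulum chaperone genes, 10 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 6.28e-07; adjusted p = 0.346 with an estimated correlation). Hspa5, encoding BiP, fell from 715 ± 77.5 to 471 ± 35.9 CPM (adjusted p = 0.00202). Of 18 heat shock genes, 6 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 1.85e-07; adjusted p = 0.346 with an estimated correlation), with Hspa8 at 1429 ± 102 CPM in GF and 835 ± 99.3 CPM in ConvD livers (adjusted p = 0.000687).

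Female-biased liver genes fell in 6 and rose in 0 of 14 cases in these male mice (7 and 0 adjusted over the list alone; camera adjusted p = 9.38e-06; adjusted p = 0.114 with an estimated correlation). Lifr, the receptor of leukemia inhibitory factor, fell (log2 fold change -0.72, adjusted p = 0.000605), and Prlr, the prolactin receptor, fell (log2 fold change -0.42, adjusted p = 0.0106). Of 18 hepatocyte markers, 6 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 8.77e-05; adjusted p = 0.179 with an estimated correlation). Cps1 of the urea cycle fell from 5449 ± 771 to 3421 ± 409 CPM (adjusted p = 0.00263). Ttr rose (log2 fold change 0.36). Albumin, Alb, gave 0.01 on the same scale (adjusted p = 0.972). In all, camera with a preset correlation shifted 18 of 47 lists, 9 up and 9 down. Other splits of the same 6 livers into 3 and 3 shifted up to 21 lists, while they called at most 5 genes.

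The comparison of GF+SCFA with GF livers asks which transcripts differ when short-chain fatty acids are given without a microbiota. It called 5 genes of 12037. Manf, an endoplasmic reticulum stress protein, rose from 51.4 ± 8.27 to 79.8 ± 3.89 CPM (SD, n = 3 each; log2 fold change 0.63, SE 0.10, adjusted p = 0.0397). Sipa1l2 fell from 9.28 ± 1.36 to 3.65 ± 0.483 CPM (log2 fold change -1.35, SE 0.15, adjusted p = 0.00293), and the fibrillar collagen gene Col3a1 fell from 25.8 ± 5.00 to 14.7 ± 0.683 CPM (log2 fold change -0.82, adjusted p = 0.0397). Ppfibp1 (-0.52) and the adhesion molecule gene Alcam (-0.52) also fell, each with an adjusted p = 0.0397. At an unadjusted p under 0.05 there were 1477 genes, and the groups did not overlap in 17.9% of genes, where chance gives 10% on average. The share was not computed for other splits of these livers, so the excess is not read as an effect of the supplement. DESeq2 called 82 genes, 34 higher and 48 lower, with these 5 among them. Each of the 5 calls was lost in at least 1 of 9 fits without a liver (Sipa1l2 only without GF+SCFA replicate 2, adjusted p = 0.0507). Col3a1 and Ppfibp1 lost theirs in 8 of these fits, Manf in 7 and Alcam in 6. Without GF replicate 3, 173 genes were called (63 higher, 110 lower), again with these 5 among them. Without any other single liver 0 to 4 were.

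Camera with the preset correlation shifted 12 lists in GF+SCFA livers, 7 up and 5 down, with 1 or 0 changed genes in each. Other splits of these 6 livers shifted up to 16. Nuclear genes of the mitochondrial respiratory chain had a positive log2 fold change in 51 of 54 cases, with a median of 0.14 and 0 genes passing (0 adjusted over the list alone; camera adjusted p = 1.99e-09; adjusted p = 0.511 with an estimated correlation). Of 21 endoplasmic reticulum chaperone genes 19 were positive and 1, Manf, passed (5 adjusted over the list alone; camera adjusted p = 1.89e-07; adjusted p = 0.511 with an estimated correlation). Genes of fatty acid oxidation had a median log2 fold change of 0.12 with 35 of 41 positive and 0 passing (0 adjusted over the list alone; camera adjusted p = 2.05e-05; adjusted p = 0.603 with an estimated correlation). For cholesterol synthesis 1 of 24 genes was positive, the median was -0.21 and 0 passed (3 lower adjusted over the list alone; camera adjusted p = 1.09e-07; adjusted p = 0.533 with an estimated correlation). Cholangiocyte markers had a median of -0.52 over 9 genes with 0 passing (4 lower adjusted over the list alone; camera adjusted p = 1.12e-05; adjusted p = 0.184 with an estimated correlation). Stellate cell and fibroblast markers had a median of -0.15 over 16 genes, of which Col3a1 passed (4 lower adjusted over the list alone; camera adjusted p = 0.000877; adjusted p = 0.184 with an estimated correlation). Fry passed the stellate list alone (adjusted p = 0.00273). Mesothelial markers had a median of -0.97, with 0 of 4 positive and 0 passing (2 lower adjusted over the list alone, camera adjusted p = 0.000561, and adjusted p = 0.343 with an estimated correlation). Of interferon-stimulated genes 10 of 37 were positive and 0 passed (1 lower adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.792 with an estimated correlation). Kupffer cell and macrophage markers were positive in 13 of 16 cases with 0 passing (0 adjusted over the list alone, camera adjusted p = 0.0196, and adjusted p = 0.792 with an estimated correlation). Targets of CAR and PXR were positive in 27 of 34 cases with 0 passing (0 adjusted over the list alone, camera adjusted p = 0.000112, and adjusted p = 0.533 with an estimated correlation). Glucocorticoid and fasting genes were positive in 16 of 20 cases with 0 passing (0 adjusted over the list alone, camera adjusted p = 0.00172, and adjusted p = 0.792 with an estimated correlation). Iron and heme genes were positive in 16 of 25 cases with 0 passing (1 higher adjusted over the list alone, camera adjusted p = 0.0411, and adjusted p = 0.343 with an estimated correlation). Of 4 tested receptors and carriers of short-chain fatty acids, 0 passed in this comparison (1 higher adjusted over the list alone; camera adjusted p = 0.109; adjusted p = 0.511 with an estimated correlation). The monocarboxylate carrier Slc16a1, not the member higher over the list alone, was 22.6 ± 0.42 CPM in GF and 22.1 ± 0.892 CPM in GF+SCFA livers. In ConvD livers Slc16a1 was called higher than in GF livers (log2 fold change 0.343 to 0.499 over fits without 1 liver), a call lost in 2 of 9 such fits. It was also called higher than in GF+SCFA livers (0.378 to 0.536), a call lost in 0 of 9.

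The direct comparison of ConvD with GF+SCFA livers asks how a microbiota differs from the supplement alone. Of 11 monocyte and neutrophil markers 6 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 5.9e-08, and adjusted p = 0.161 with an estimated correlation). Of 20 NRF2 and glutathione genes 8 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 4.53e-05, and adjusted p = 0.161 with an estimated correlation). Of 18 gluconeogenic genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 6.36e-06, and adjusted p = 0.244 with an estimated correlation). In total 2216 genes changed, 1136 higher and 1080 lower, and 287 of these at least 2-fold. Of the 1544 genes called in ConvD against GF, 1079 (69.9%) were called in the same direction here and 0 in the opposite one. Both comparisons use the same 3 ConvD livers, so these shared calls are not independent and can arise without any effect of the supplement. Without GF+SCFA replicate 2 the count was 1383, without GF+SCFA replicate 3 it was 1400 and without ConvD replicate 2 it was 1465. With library totals in place of TMM, 72.4% of 2127 calls were higher, against 51.3% in the main test, and 66.8% of 2267 calls with upper-quartile factors.

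Csad, the enzyme of taurine synthesis from cysteine sulfinate, was 38.8 ± 5.14 CPM in GF+SCFA and 149 ± 23.6 CPM in ConvD livers (SD, n = 3 each; log2 fold change 1.94, SE 0.12, adjusted p = 7.69e-06). It was 59.2 ± 3.44 CPM in GF livers. Aqp8 was 5.75-fold higher in ConvD (adjusted p = 0.00429), Spon2 5.47-fold (adjusted p = 8.91e-06), Gsta1 4.33-fold (adjusted p = 0.00243) and 3010026O09Rik 4.23-fold (adjusted p = 1.45e-05). Fam198a was 4.01-fold and Tiam2 3.58-fold higher. Chrna4 (8.18-fold), Cish, a suppressor of cytokine and growth hormone signalling (6.00-fold), and the interferon-induced GTPase gene Tgtp1 (3.76-fold) passed too. Among the decreases, Cry1 fell from 11.8 ± 1.18 to 3.24 ± 0.727 CPM (log2 fold change -1.87, SE 0.17, adjusted p = 1.91e-05). Zbtb16 (-2.74), Cyp2c69 (-2.49), Cyp2c40 (-2.46), Ddit4 (-2.38), Eif4ebp3 (-1.97) and Hsph1 (-1.88) fell in this comparison as in that with GF. Gm6907 (-1.74), Map3k13 (-1.74) and Lonrf3 (-1.68) completed the list. Of these 20 genes, 12 kept the call whichever liver was left out. Of the 9 such fits, Cish and Tgtp1 lost it in 6, Chrna4 and Cyp2c69 in 4 and Hsph1 and Map3k13 in 3. Gm6907 lost it in 2 and Zbtb16 in 1. The adjusted p reached 0.109 (Cish without GF+SCFA replicate 2).

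Interferon-stimulated genes rose in 28 of 37 cases and fell in 0 (31 and 0 adjusted over the list alone; camera adjusted p = 1.16e-19; adjusted p = 0.161 with an estimated correlation). Tap1 rose from 13.6 ± 0.51 to 31.9 ± 5.01 CPM (adjusted p = 8.53e-05). Endoplasmic reticulum chaperone genes fell in 12 of 21 cases and rose in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 5.49e-14; adjusted p = 0.161 with an estimated correlation). Manf was 79.8 ± 3.89 CPM in GF+SCFA and 35.3 ± 1.85 CPM in ConvD livers (log2 fold change -1.17, adjusted p = 1.36e-05), and Hspa5 was 927 ± 93.0 and 471 ± 35.9 CPM (adjusted p = 5.18e-05). Of 54 respiratory chain genes 16 were lower in ConvD and 0 higher (21 and 0 adjusted over the list alone, camera adjusted p = 2.64e-06, and adjusted p = 0.355 with an estimated correlation). An example was Cox5b of cytochrome c oxidase (log2 fold change -0.31, adjusted p = 0.0051). The list median was -0.167 with TMM and -0.096 with library totals. In ConvD against GF livers 0 of these 54 genes passed (0 adjusted over the list alone, camera adjusted p = 0.209, and adjusted p = 0.88 with an estimated correlation). Stellate cell and fibroblast markers rose in 6 of 16 cases and fell in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0553; adjusted p = 0.244 with an estimated correlation). Col3a1 was 1.81-fold higher in ConvD (adjusted p = 0.000531), and Col1a2 1.62-fold (adjusted p = 0.00282). Clock genes fell in 9 and rose in 3 of 21 cases (9 and 3 adjusted over the list alone; camera adjusted p = 0.000233; adjusted p = 0.161 with an estimated correlation): Nr1d1 (1.37), Dbp (0.85) and Bhlhe41 (1.76) were higher in ConvD, and Nfil3 (-1.48) and Arntl (-0.90) lower. In all 21 lists shifted, 9 up and 12 down, and other splits of these 6 livers shifted up to 18.

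**Figure D3:**
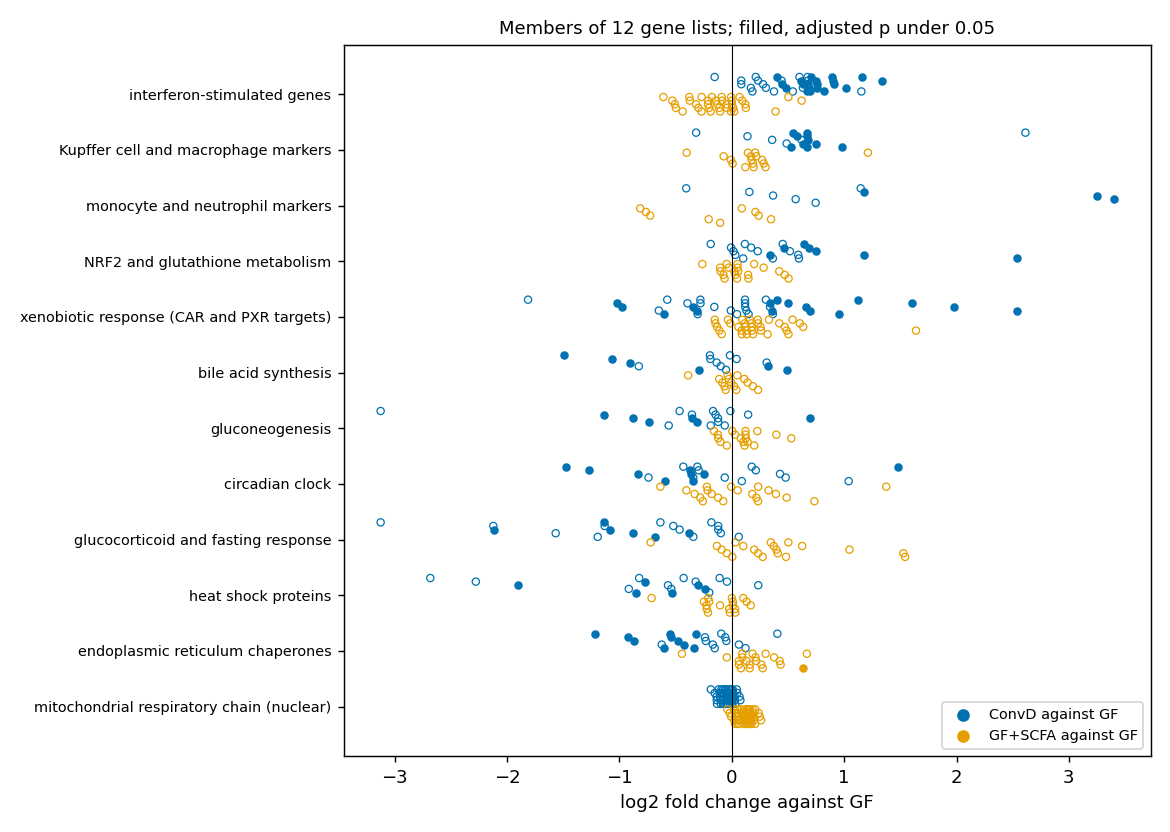
Log2 fold changes against GF of the tested members of 12 fixed gene lists in ConvD (blue) and GF+SCFA (orange) livers; each circle is a gene, filled where the adjusted p is under 0.05, and Ltf and Ngp, without counts in some groups, are left out. In ConvD 20 of 37 interferon-stimulated genes are filled, and in GF+SCFA 1 gene of these lists, Manf.

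Both treatments were compared with the same 3 GF livers, which makes their fold changes covary without any effect. Across 12037 genes the covariance of the log2 fold changes was 0.0186, and it was 0.0249 on average in 100 simulations without effects (95% of them between 0.0197 and 0.0319). The difference was -0.00631. The correlation across genes, which are not independent replicates, was 0.176 against 0.499 in the simulations. Changes in ConvD livers alone, which the simulations leave out, also lower this correlation, so the 2 values do not show whether the responses agree. With only 2 shared GF livers the simulated covariance is larger. Without GF replicate 3 the covariance was 0.0486, within 95% of its own simulations (0.0318 to 0.0524), and without GF replicate 1 it was 0.0399 (0.0312 to 0.0484). Without GF replicate 2 it was 0.0288, below the range of 95% of its simulations (0.0326 to 0.0494). With edgeR 0 genes were called the same way in both comparisons, where independent lists would share 0.0593 higher and 0.276 lower genes and the simulations shared 0.14 genes. DESeq2 called 13 genes the same way and 14 in opposite ways, and at an unadjusted p under 0.05 there were 359 and 202. Without GF replicate 3 edgeR called 46 genes the same way, where 100 simulations without effects gave at most 3. These simulations leave out the effects of both treatments, so the excess is not read as a shared response. Of the 5 genes called in GF+SCFA livers, Manf and Ppfibp1 were also called in ConvD livers, in the opposite direction (log2 fold change -0.54 and 0.64).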

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

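The counts for ConvD against GF and ConvD against GF+SCFA stayed within 1.5 times under every other scaling, either filter, DESeq2, voom, the length offset, non-robust spreads and the 6 samples alone. Against a fold change of 1.2 they were 292 and 663 (1 for GF+SCFA against GF), and limma-trend on TPM gave 1019 and 972 for ConvD against GF; testing for a larger change explains the former, and for the latter the cause was not tested. For GF+SCFA against GF the 5 calls became 9 with library totals, 24 without a filter, 82 with DESeq2 and 1 with voom, either TPM scale or non-robust spreads; the cause was not tested. Without a filter, which lets in genes of a few counts, the covariance was 0.243 and 6 genes were called the same way. With GF samples split so that no control was shared, a choice made after seeing the data, the covariance averaged -0.00871 over 6 splits (-0.0230 to 0.00278). It was taken on differences of mean log2 CPM, which shrink low genes more than the edgeR fold changes of the main covariance. The drop from the main value is therefore not due to the removal of shared controls alone. List counts were 0, 0 and 0 with an estimated correlation. With fry they were 18, 1 and 24, not in every case the lists that camera passed. With 1 sample left out the ranges were 849 to 1466 genes for ConvD against GF, 0 to 173 for GF+SCFA against GF and 1383 to 2393 for ConvD against GF+SCFA. Lists ranged over 15 to 22, 10 to 21 and 17 to 26, the covariance over 0.0136 to 0.0486 and genes called the same way over 0 to 46. Of 283 named calls, 188 held in all 9 such fits, 0 changed sign, and 5 lost the threshold with DESeq2 and 23 with library totals. Replicate numbers are shared by the groups, and the labels do not say what they mark. Correlations of same-numbered samples' deviations ran from -0.066 to 0.139, and 5 of 9 samples correlated best with their own number. Between GF and GF+SCFA samples the same-numbered values were 0.086, 0.077 and 0.139 and the others -0.104 to 0.024, so a pairing of these 2 groups cannot be excluded. With the replicate block 1514, 5 and 2195 genes were called, and 22 named calls ended; for GF+SCFA against GF 3 of the 5 main calls were kept, and 1 with the 6 samples alone, which called 4. In simulations with these depths, spreads and 3 samples per group, 6% to 16.2% of genes with the smallest simulated change were recovered.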

Other observations

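The gene and list tests in this part were planned, and the tests of explanations for the 3 patterns and the counts over other splits and regroupings were chosen after the results were seen. Other gene groups differed between ConvD and GF livers in a few members each. Of 16 histone acetyltransferase genes 4 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0461; adjusted p = 0.535 with an estimated correlation), among them Crebbp (log2 fold change -0.52, adjusted p = 0.00952) and Ep300 (-0.36, adjusted p = 0.0139, up to 0.0617 without ConvD replicate 2), whose products acetylate histones at enhancers. The DNA methyltransferase Dnmt3a rose 1.38-fold (adjusted p = 0.0121). Of 22 genes of one-carbon and methionine metabolism 4 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0638; adjusted p = 0.644 with an estimated correlation), including Ahcy, which hydrolyses S-adenosylhomocysteine (2791 ± 251 to 1854 ± 80.9 CPM, adjusted p = 0.00114). Of 27 cell cycle genes 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0261; adjusted p = 0.297 with an estimated correlation). Cdc20 rose from 0.205 ± 0.105 to 0.902 ± 0.124 CPM (adjusted p = 0.00724), and Ccne2 fell (log2 fold change -1.35, adjusted p = 0.00685). Of 25 iron and heme genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.59; adjusted p = 0.735 with an estimated correlation). Besides Slc40a1, the biliverdin reductase Blvrb (1.31-fold, adjusted p = 0.00304) and Hfe (1.21-fold, adjusted p = 0.0221, up to 0.0887 without GF replicate 1) rose. The transferrin receptor Tfrc fell (log2 fold change -1.19, adjusted p = 0.0338, up to 0.103 without ConvD replicate 1), a call lost in 6 of 9 fits without 1 liver.

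Immediate early genes, which respond quickly to stress and handling, had a median log2 fold change of -0.49 in ConvD against GF livers, with 3 of 19 positive. Of them 1, Klf4, fell (-0.85, adjusted p = 0.0417, up to 0.181 without GF replicate 3), a call lost in 7 of 9 fits without 1 liver. Adjusted over the list alone 0 passed (camera adjusted p = 0.209, and adjusted p = 0.88 with an estimated correlation). Against GF+SCFA the median was -0.42, with 3 of 19 positive and 0 passing (0 adjusted over the list alone; camera adjusted p = 0.0568; adjusted p = 0.688 with an estimated correlation).

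Cell type markers did not all move alike in ConvD livers. Of 16 sinusoidal endothelial markers 0 rose and 1, Lyve1, fell (log2 fold change -0.85, adjusted p = 0.0359, up to 0.113 without ConvD replicate 1). The Lyve1 call was lost in 7 of 9 fits without 1 liver, and 0 markers passed adjusted over the list alone (camera adjusted p = 0.824, and adjusted p = 0.964 with an estimated correlation). Of 16 stellate, 9 cholangiocyte, 12 T and NK cell and 5 dendritic cell markers, 0 passed, and 0 passed adjusted over the list alone (camera adjusted p = 0.937, 0.517, 0.294 and 0.853; adjusted p = 0.968, 0.825, 0.735 and 0.964 with an estimated correlation). Of 5 adipocyte markers 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0122, and adjusted p = 0.179 with an estimated correlation). They were Pparg, a regulator of fat storage (log2 fold change 1.33, adjusted p = 0.0339, up to 0.103 without GF replicate 2), and Car3 (0.37, adjusted p = 0.025, up to 0.0933 without GF replicate 1). Pparg lost the call in 7 and Car3 in 4 of 9 fits without 1 liver. Of 21 pericentral genes 2 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.89; adjusted p = 0.968 with an estimated correlation). Lgr5, a Wnt target of pericentral hepatocytes, fell (log2 fold change -0.71, adjusted p = 0.0108), while Lgals1 in the same list rose 2.52-fold (adjusted p = 0.00649). Of 24 male-biased genes 1 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.139, and adjusted p = 0.844 with an estimated correlation). The riser, Mup20, a male-biased urinary protein of a near-identical family, was at 5872 ± 1763 CPM in GF and 10038 ± 453 CPM in ConvD livers (adjusted p = 0.0161, up to 0.0621 without ConvD replicate 2).

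In ConvD against GF livers 10 of 16 macrophage and 5 of 11 monocyte and neutrophil markers rose (adjusted p = 0.297 and 0.114 for the lists with an estimated correlation). A lower share of hepatocyte RNA would raise the markers of all other cells, but sinusoidal endothelial and stellate markers had a median log2 fold change of 0.003 over 32 genes. This was 0.623 below that of the macrophage markers (SE 0.192 over genes). The SE takes the genes as independent, while the macrophage list had an estimated correlation of 0.592, so it is too small and does not measure the spread between livers. More blood could bring neutrophil transcripts: the globin sum was 0.95, 4.56 and 2.90 times the GF mean in the ConvD livers and the sum of the 5 neutrophil genes 4.86, 7.41 and 4.44 times. These 5 are the list members called higher in ConvD against GF, so the rise of their sum was fixed by that choice. It also pushes their ratio to the globins upward. The log2 ratio of the sums was 1.229 higher in ConvD, with an SE of 0.657, so blood cannot be told apart from tissue neutrophils with 3 livers. More macrophages per liver, or more of these transcripts in each, remain open as responses to colonisation, and neither was tested.

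In ConvD against GF livers 8 of 21 clock, 6 of 20 glucocorticoid and fasting and 6 of 18 heat shock genes fell (adjusted p = 0.106, 0.387 and 0.346 for the lists with an estimated correlation). No single liver accounts for it: the median log2 fold change of the 58 tested members was -0.43, and the value nearest to 0 with 1 library left out was -0.37. A different time of day at dissection, which moves clock genes both ways, is a candidate explanation: against GF 8 clock genes fell and 1, Bhlhe41, rose (10 and 2 adjusted over the list alone), so time of day cannot be told apart from colonisation there, as the labels give no times. Against GF+SCFA 9 fell and 3 rose (Nr1d1, Dbp and Bhlhe41), as a different time of day would give, and as an effect of the microbiota on feeding, corticosterone or the clock would too, which was not tested. In GF+SCFA against GF 0 clock genes passed, and 2 were higher and 4 lower adjusted over the list alone in livers without a microbiota.

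The few calls in GF+SCFA livers may reflect where GF replicate 3 lies. It correlated at 0.9902 to 0.9905 with the GF+SCFA libraries and at 0.9884 and 0.9895 with the other GF libraries, a mean difference of 0.0014, and without it 173 genes were called in place of 5. A swap with a GF+SCFA sample is argued against, since each GF+SCFA library correlated more with its own group than with GF replicates 1 and 2, by at least 0.0014. A single wrong label, or a GF mouse that differed in stress or feeding at dissection, stays open: its Mt1 was 82.6 CPM against 18 and 24.8 CPM in the other GF livers and 58.2 to 134 CPM in GF+SCFA livers (a gene chosen after its values were seen).

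The 10 splits of 6 livers are too few for a share under 0.05. The real split gave 1544, 5 and 2216 genes in the 3 comparisons, and the highest of the other splits 5, 1 and 3, so the real one was in each case the only 1 of 10 with as many. For shifted lists the real splits gave 18, 12 and 21, and the highest of the others 21, 16 and 18; 3, 4 and 1 of the 10 splits gave as many. Of 100 regroupings of the 9 livers, the real one included, 82 gave a covariance of fold changes as large as the real 0.0186 (highest other 0.136), but this count does not test the real grouping. All other regroupings but 2 place ConvD livers in the control group or in both arms, which carries the ConvD difference into the covariance: it was 0.131 to 0.136 in the 3 whose control group was the 3 ConvD livers. The 2 that keep these livers together in an arm gave 0.0277 and 0.0443, and are too few for a share under 0.05. For genes called the same way the real count is 0, so all 100 gave as many by construction and the count tests nothing. The highest other, 1072, came from those 3 regroupings (883 to 1072 genes), which points to the separation of the ConvD livers from the rest, and the others gave at most 3.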
